A study of Mus musculus with 34 samples.

How the data were processed

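Gonads of E13.5 embryos were sorted by flow cytometry into Oct4GFP-positive PGCs and Oct4GFP-negative soma and cryopreserved, and CUT&RUN was run on 1000 cells per library with an H3K9me2 or IgG antibody and 18 PCR cycles, per the labels' protocols. Libraries were grouped by cell type, antibody and vitamin C state as the labels give them. Reads were trimmed with Trim Galore 0.4.0 and aligned with Bowtie2 2.2.5, and Picard and the mm10 build are named, per the submitters' processing notes. How reads were counted over genes and repeat families, which features were filtered and how libraries were scaled is not given in the sources used here.

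The files analysed were 4 tables of a voom and limma comparison, for genes and for repeat families in soma and in PGCs, per the file headers. The headers do not name the antibody, and the tables were taken as those of the H3K9me2 libraries. The IgG libraries have the same numbers per group, so library numbers cannot tell these antibodies apart. The authors' deposited tables give each log2 fold change and average on the log2 scale, the average as log2 CPM. The moderated t statistic is a score in the authors' deposited tables, beside a p-value, a p-value adjusted by Benjamini-Hochberg and the B statistic, a natural log of odds. The adjusted p-values were recomputed from the deposited p-values and matched. The p-values follow from t with 143530 degrees of freedom for soma genes, 216168 for PGC genes, 7410 for soma families and 29.6 for PGC families. All but the last are the residual degrees of freedom, 5 in soma and 8 in PGCs, pooled over all features. No table holds values per library, so sample plots, leaving out libraries, splits of the samples and a comparison with IgG were not run. With the tables taken as H3K9me2, the IgG libraries were not used here.

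The direction of the contrast is not given in the sources used here and was read from the tables. The standard error of a low-count feature depends on how many libraries lie on each side of the subtraction. For soma genes 4 subtracted and 3 other libraries left a misfit of 0.488% and the reverse 1.99%, and for soma families 0.314% and 6.41%, so soma values are withdrawn minus supplied. In 1 simulated soma data set the right direction also fitted better, by a smaller margin (3.16% against 3.59%, and 3.15% against 3.83% with the contrast turned). PGCs have 5 libraries on each side, so their sign cannot be read in this way, and it was assumed to follow that of soma.

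Depth per library was not given, and a minimum for its geometric mean was derived. Averages of log2 CPM over whole reads can take only certain steps, so ratios between the lowest averages, up to 400, were compared with ratios of odd whole numbers with a denominator under 5000, within a relative tolerance of 3e-11. For soma genes 310 distinct averages met these steps for 7 libraries and 0 did not, with 277 and 0 for the 10 libraries of PGC genes. Assuming 6 soma libraries, 8 did and 467 did not. This put the geometric mean effective library size at 1512598 or more for soma genes, 613601 for PGC genes, 2130351 for soma families and 792226 for PGC families. Effective sizes include the authors' scaling, and PCR reads are not independent molecules.

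Each comparison used the statistics of the authors' deposited tables, by limma, with an adjusted p under 0.05, and the standard error was the log2 fold change divided by t. Changes relative to the median were tested after subtracting the table's median log2 fold change, with the same standard errors and degrees of freedom and a new Benjamini-Hochberg adjustment. The difference between soma and PGCs was divided by the root of the summed squared standard errors and tested, two-sided, with Satterthwaite degrees of freedom over 26721 shared genes and 1445 shared families. This takes the soma and PGC estimates as independent, and any pairing of their libraries could not be used. Gene lists and repeat classes were tested with limma's cameraPR on t, two-sided, at a correlation between genes of 0.01, adjusted over 26 gene lists and 11 repeat classes per table. No correlation could be estimated without values per library, so 0.05 was used in its place as the alternative. Repeat classes were assigned by family name, and 10000 random lists matched on size and average served as a further comparison. Lists with fewer than 5 measured members were not tested.

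Gene lists, comparisons and the rule for named features were fixed before the data were examined. Named are the 10 features with the smallest p in each direction past the threshold, up to 5 where fewer passed, the member of each list with the smallest p, and the leading features of the difference. Also named throughout are Dazl, Stra8, Sycp1, Sycp3, Ddx4, Mael, Pou5f1, Tet1, Gulo, Slc23a2, IAPEz-int, MERVL-int and GSAT_MM. Predicted gene models, Rik clones and microRNA genes are counted but not used as examples, and L1MdA_I and L1MdT_I, also on that list, are not among the measured families. Tdgf1 was named after its value was seen, as were L1Md_A, L1Md_T and L1Md_Gf in the place of young LINE-1 families, whose planned name pattern matched 0 families. Symbols were matched to RefSeq mm10 gene positions by symbol or synonym for 27347 soma genes and 25837 PGC genes.

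The procedure was tested on simulated data. In simulated libraries of 28696 soma genes, 200 of them changed, a shift of 1.04 put in came back as 1.03, and 7 of 111 calls relative to the median were false; for 27019 PGC genes 1 of 101 was. With 200 features changed at the real standard errors, 15.5% of 2-fold, 80.5% of 4-fold and 95% of 8-fold changes were recovered for soma genes. For PGC genes 0%, 43.5% and 89% were. For PGC families these shares were 0%, 69.5% and 96.5%. In the list test, run on random values, a list with a shift passed and 3.6% of 500 lists without one passed an unadjusted threshold of 0.05. Random values do not hold the correlation within real gene clusters or repeat classes, so this share does not give the false positive rate of their calls. Alternatives were other thresholds, a Bonferroni adjustment, a minimum fold change, a filter on the 25% of features with the lowest averages, centring, other list statistics and backgrounds, and, chosen after the data were seen, residual degrees of freedom and the turned PGC sign. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.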

Results

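H3K9me2, a histone mark of repressed chromatin, was profiled by CUT&RUN in gonads of E13.5 female mouse embryos. In this assay an antibody directs a nuclease to release the DNA around the mark. The embryos lacked Gulo, the enzyme of the last step of vitamin C synthesis, so vitamin C came from the maternal diet and was either supplied or withdrawn. Primordial germ cells (PGCs), the precursors of eggs and sperm, were sorted as Oct4GFP-positive cells, and the Oct4GFP-negative remainder of the gonad was taken as soma. The 34 libraries comprised 5 supplied and 5 withdrawn H3K9me2 libraries of PGCs, 4 supplied and 3 withdrawn of soma, and the same numbers with control IgG. The analysis rests on 4 tables of statistics, covering 28706 genes and 1482 repeat families in soma and 27021 genes and 1456 families in PGCs. That these tables are of H3K9me2 rather than IgG is assumed throughout, since their headers name no antibody and the group sizes are the same. From the lowest averages in the authors' deposited tables, the geometric mean effective library size for genes was at least 1512598 reads in soma and 613601 in PGCs. At that depth the median gene had about 15.9 reads per library in soma and 7.03 in PGCs.

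The first comparison asked how H3K9me2 over genes differed in soma when vitamin C was withdrawn. On the scale of the authors' deposited table, the H3K9me2 signal was higher over most genes, and rose and fell refer to the signal over a gene on that scale. How the libraries were scaled is not given in the sources used here. In the authors' deposited table, 19569 of the 28706 genes rose and 29 fell past an adjusted p of 0.05, and the median gene stood 2.06-fold higher, a log2 fold change of 1.04. Erdr1, a gene at the end of the X chromosome with near-identical copies, rose by 3.11 ± 0.22 (log2, SE; adjusted p = 7.33e-42), and Malat1, an abundant nuclear non-coding RNA, by 2.84 ± 0.27 (adjusted p = 1.99e-22), per the authors' deposited table. Tet1 (mm10 chromosome 10, 62804570 to 62887469), an enzyme that oxidises 5-methylcytosine with vitamin C as a cofactor, rose by 1.95 ± 0.24 (adjusted p = 6.43e-12) in the authors' deposited table. Mki67, the Ki-67 proliferation antigen, rose by 2.16, Hjurp, the chaperone of centromeric histone CENP-A, by 2.01 and Smo, the Hedgehog signal transducer, by 1.84 in the authors' deposited table. The same authors' deposited table gave 2.04 for Zfp534, 1.73 for Znf41-ps, 1.59 for Arfgef3 and 1.51 for Sfi1, of which Zfp534, Znf41-ps and Sfi1 have close copies whose reads may be shared.

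Among the few genes that fell, Rn7s2 and Rn7s1, copies of the 7SL RNA of the signal recognition particle, had log2 fold changes of -0.67 and -0.65 in the authors' deposited table. Acacb, an acetyl-CoA carboxylase, stood at -0.49, Lig1, a replicative DNA ligase, at -0.56, and Izumo1, the sperm protein that binds the egg, at -0.63 in the authors' deposited table. Zfp949 at -0.52, Ybx3 at -0.52, Dpp9 at -0.51, Sepsecs at -0.53 and Y-linked Usp9y at -0.85 also fell in the authors' deposited table. Apart from Usp9y, at 4.25, these named genes had average log2 CPM from 7.23 (Izumo1) to 10.97 (Acacb). The median gene stood at 3.40. Whether their reads come from repeats or shared sequence within the gene was not tested. All 37 measured Y-linked genes together had a median of 0.049 in the authors' deposited table, against 1.04 for all genes, in libraries labelled female.

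Relative to the median shift of 1.04, 14 soma genes lay higher and 374 lower past an adjusted p of 0.05, against 19569 and 29 on the scale of the authors' deposited table. Erdr1 stood 2.07 above the median (adjusted p = 2.89e-17), Malat1 1.80 (adjusted p = 1.56e-08) and Tdgf1, an embryonic Nodal co-receptor, 2.02 (adjusted p = 0.00449). Mki67 stood 1.12 above it (adjusted p = 0.0172), Zfp534 1.00 (adjusted p = 0.0175) and Tet1 0.91 (adjusted p = 0.0197). Sfi1, Smo, Znf41-ps, Arfgef3 and Hjurp did not pass relative to the median. With the 5 residual degrees of freedom of the 7 soma libraries, in place of the pooled degrees of freedom behind the authors' deposited table, 9217 genes rose and 0 fell, so the calls of fallen genes rest on that pooling. The 14 and 374 calls relative to the median also used the pooled degrees of freedom and were not tested with 5.

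**Figure D1:**
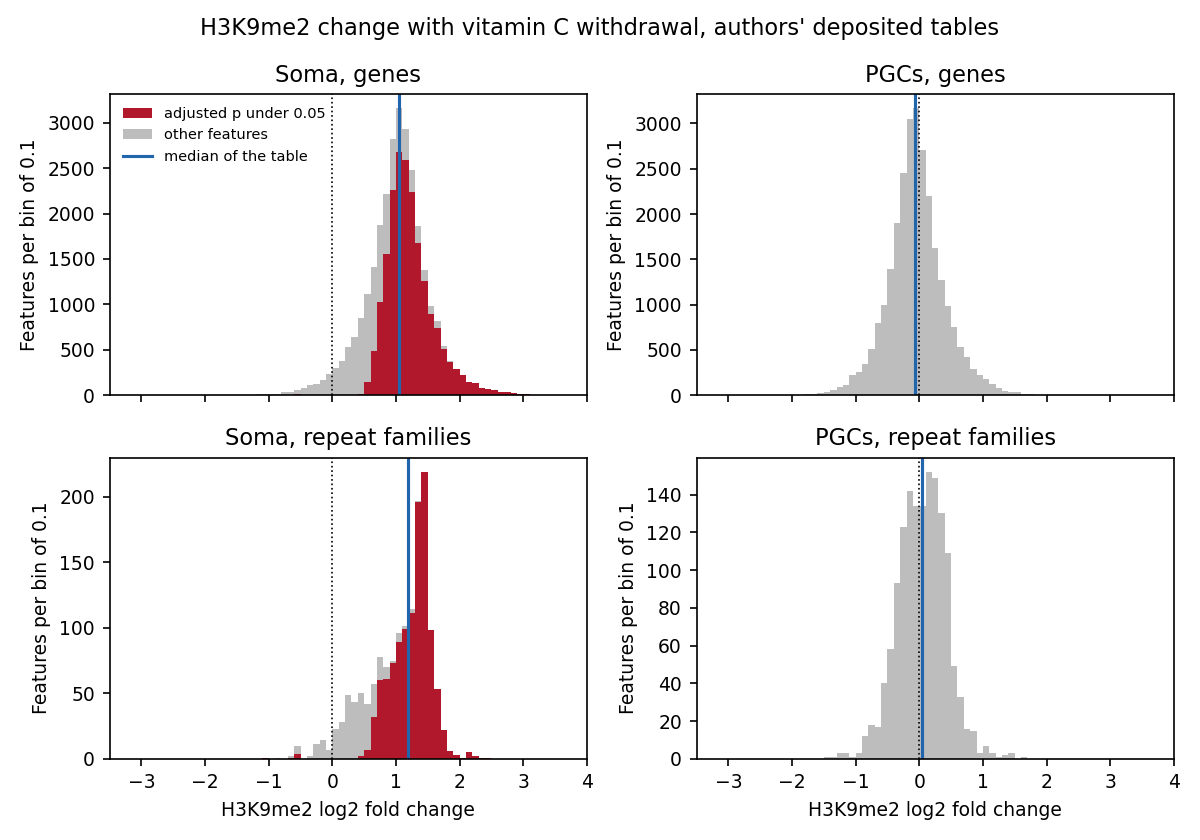
Histograms of the H3K9me2 log2 fold change per gene or repeat family in soma (left) and PGCs (right), with features past an adjusted p of 0.05 in red, others in grey, the table's median as a blue line and 0 as a dotted line. The soma medians lie at 1.04 and 1.18 and the PGC medians at -0.064 and 0.050, and no PGC feature passed. The sign of the PGC axis is assumed to follow that of soma, and the antibody is assumed to be that against H3K9me2.

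Many genes of the germline rose in soma. Of 43 measured germline genes whose promoters are known to be kept silent by DNA methylation, 34 rose in the authors' deposited table and 35 when adjusted over the list alone, with a median of 1.04, that of all genes. Nlrp4c rose by 1.44 and Tdrd1, a piRNA pathway protein, by 1.60 in the authors' deposited table. Ddx4, a germ cell RNA helicase, rose by 0.99, Mael, a piRNA factor, by 0.91 and Stra8, the meiotic gatekeeper, by 1.28 in the authors' deposited table. Dazl, a germ cell RNA-binding protein, stood at 0.60 ± 0.34 and did not pass (adjusted p = 0.0978) in the authors' deposited table. Of 37 meiosis genes 30 rose, also 30 adjusted over the list alone, among them Sycp2 by 1.36 and Sycp1 by 0.94, while Sycp3 stood at 0.34 ± 0.42 (adjusted p = 0.457) in the authors' deposited table. Ddx4, Mael, Sycp1, Sycp3 and Dazl lay below the median of all genes, and none of these differed from it past the threshold. Of 29 PGC and pluripotency genes 22 rose, and 22 adjusted over the list alone, including Pou5f1, whose regulatory sequence drives the Oct4GFP reporter, by 1.95 in the authors' deposited table. None of these 3 lists differed from the other genes in limma's cameraPR test (adjusted p = 0.162, 0.423 and 0.929).

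Many marker genes of the cell types that the Oct4GFP-negative gate can hold also rose, as did 19569 of all 28706 soma genes in the authors' deposited table. None of the 6 cell type lists or of the 4 lists of imprinted genes, DNA methylation, H3K9 enzymes and vitamin C handling differed from other genes in cameraPR on the deposited t, the lowest adjusted p = 0.118 being that of DNA methylation. In cameraPR the stromal list lay lower on centred t, by fold change and without the lowest averages (adjusted p = 0.0178, 0.0494 and 0.0286). It did not pass by ranks, at a correlation of 0.05 or with the reduced background (adjusted p = 0.142, 0.453 and 0.224). Nor did it pass against random lists of like average (adjusted p = 0.0723). Of the supporting cell genes, 13 of 21 rose in the authors' deposited table, including Runx1 by 1.34, with 10 of 17 stromal genes, including Dcn by 1.39, and 14 of 14 endothelial genes, including Pecam1 by 1.20. These counts were 13, 10 and 14 adjusted over the list alone. Blood genes rose in 11 of 16 cases, including Ptprc by 1.22, steroid and testis genes in 10 of 15, including Cyp11a1 by 1.54, and mesonephric genes in 8 of 11, including Ret by 1.44, in the authors' deposited table. Adjusted over the list alone 11, 11 and 8 of these genes rose. Of the imprinted genes 28 of 38 rose, among them Slc22a3 by 1.63 and Igf2r by 1.55, in the authors' deposited table. Of the DNA methylation machinery 19 of 22 rose, among them Zfp57, the guardian of imprints, by 2.27 and Tet2 by 1.21, in the authors' deposited table. Imprinted and DNA methylation genes rose in 28 and 20 cases adjusted over the list alone. Of the H3K9 enzymes 19 of 23 rose, with Kdm4b, an H3K9 demethylase, at 1.36, and of the vitamin C handling genes 17 of 25, with Txnrd1 at 1.47, in the authors' deposited table, or 19 and 18 adjusted over the list alone. Gulo rose by 0.84 ± 0.34 (adjusted p = 0.0244) and the vitamin C transporter Slc23a2 stood at 0.51 ± 0.24 (adjusted p = 0.0521) in the authors' deposited table; all libraries carry the same Gulo genotype, so Gulo does not test the labels.

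Hox genes, which pattern the body axis, had the lowest median in soma among the 26 gene lists tested. Their median log2 fold change was 0.24, 0.80 below that of all genes, 2 of 31 rose in the authors' deposited table (1 adjusted over the list alone), and 30 of 31 lay below the median gene (cameraPR adjusted p = 1.12e-11). Hoxc4 rose by 1.60 and Hoxa10 by 0.81 in the authors' deposited table, Hoxa10 lying below the median of all genes. Olfactory receptor genes had a median of 0.78, with 181 of 976 risen and 1 fallen in the authors' deposited table, 52 and 0 adjusted over the list alone, and Olfr570 at 1.44 (cameraPR adjusted p = 1.89e-26). Their cameraPR call held after centring on the median (adjusted p = 0.0136), as did that of the Hox genes (adjusted p = 4.52e-10). Hox and olfactory receptor genes lie in clusters, where neighbours may share a value. At an assumed correlation of 0.01 between genes these p-values may be too small. Clustered histone genes, a list matched by name that also takes in many H2 histocompatibility genes, and ribosomal protein, keratin-associated, defensin and microRNA genes, the last including host transcripts, also passed in the lower direction on the deposited t, which for a shift shared by most genes also follows coverage. Of their 95, 69, 20, 51 and 13 genes, 30, 10, 1, 24 and 5 rose in the authors' deposited table, and 21, 3, 1, 19 and 5 adjusted over the list alone, while 1 microRNA gene fell by both counts. Their medians lay -0.35, -0.22, -0.39, 0.017 and -0.45 from that of all genes, so the defensins did not lie lower. The 6 soma genes annotated as microRNAs, rather than as host transcripts, had a median log2 fold change of 0.029. On centred t none of the 5 passed (adjusted p = 0.0644, 0.322, 0.219, 0.918 and 0.0984). Against random lists of like average, which take coverage into account, the histone, ribosomal and microRNA lists lay lower (adjusted p = 0.0013, 0.0305 and 0.0305, the first from the smallest p that 10000 lists can give), and the keratin-associated and defensin lists did not pass (adjusted p = 0.065 and 0.82). With log2 fold change as the statistic the histone, keratin-associated and microRNA lists passed (adjusted p = 4.91e-05, 0.0134 and 0.00155), and the ribosomal and defensin lists did not (adjusted p = 0.068 and 0.837). In cameraPR without the lowest averages the histone list passed (adjusted p = 0.00232). The ribosomal, defensin and microRNA lists did not (adjusted p = 0.0521, 0.245 and 0.593), and the keratin-associated list had too few members.

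Over repeat families in soma, endogenous retroviruses had the highest medians among the 11 repeat classes tested. Of 1482 families, 1141 rose and 6 fell in the authors' deposited table, with a median log2 fold change of 1.18. IAPEz-int, the internal part of the IAP retrotransposon, rose by 1.59 ± 0.22 (adjusted p = 1.52e-10) and IAPLTR1a_Mm by 1.83 in the authors' deposited table. All 25 IAP families, 192 of 194 other ERVK, 28 of 28 ERVL, 102 of 105 MaLR and 139 of 141 ERV1 families rose in the authors' deposited table, with class medians of 1.53, 1.42, 1.42, 1.41 and 1.45. The counts adjusted over each list alone were the same, and all 5 classes lay above the other families in cameraPR (adjusted p = 8.41e-06, 8.25e-14, 0.000101, 4.49e-08 and 4.98e-10) and after centring. These 5 calls and the 7 of the soma gene lists also passed at a correlation of 0.05. RLTR10-int rose by 1.62, MT2A by 1.39, RLTR6-int by 1.65, MTD by 1.45, MTA_Mm by 1.52 and ORR1A2 by 1.55, while MERVL-int rose by 1.09, below the median family, in the authors' deposited table.

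The LINE-1 families L1Md_A, L1Md_T and L1Md_Gf rose by 1.60, 1.54 and 1.64 in the authors' deposited table, and 110 of the 131 LINE-1 families lay below the median family, and the class median was 0.96. In cameraPR LINE-1 families did not differ from the others on the deposited t values (adjusted p = 0.475) and lay below them on centred values (adjusted p = 2.11e-06). They also lay below by fold change and without the lowest averages (adjusted p = 0.00149 and 0.00464), but not by ranks (adjusted p = 0.175). Against random lists of like average, which take coverage into account, LINE-1 families did not pass (adjusted p = 0.055). GSAT_MM, the major satellite of pericentromeric heterochromatin, rose by 1.43, L2 by 1.39, URR1A by 1.51, and the SINEs RSINE1 and B4A by 1.48 and 1.43 in the authors' deposited table. The 6 families that fell were 7SLRNA at -0.58 and the simple repeats (CATTC)n, (GAATG)n, (CGATA)n, (CTATT)n and (CACTC)n at -0.55, -0.60, -1.02, -0.62 and -0.59 in the authors' deposited table. With the residual degrees of freedom alone 999 families rose and 0 fell, so these 6 calls also rest on the pooling, and at an adjusted p under 0.01 they end too. Relative to the median family, and with the pooled degrees of freedom, 0 lay higher and 130 lower past the threshold. No single family, the IAPs included, was thus shown to exceed the common shift.

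**Figure D2:**
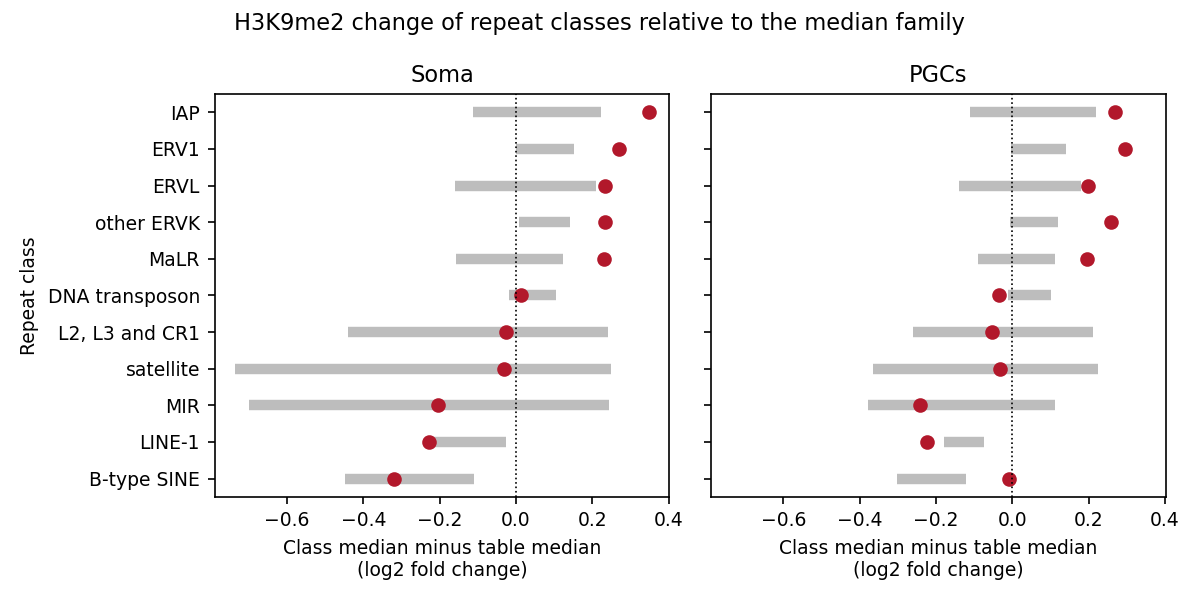
Median H3K9me2 log2 fold change of each repeat class minus the median of all families (red points) in soma and PGCs, with the middle 95% of 10000 random lists of the same size and average as grey bars. IAP, ERV1, ERVL, other ERVK and MaLR classes lie above their bars in both cell types, by 0.35 to 0.23 over the median family in soma. The PGC sign and the antibody are assumed.

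In PGCs the same question found no single gene or family that passed. Of 27021 genes and 1456 families, 0 and 0 had an adjusted p under 0.05 by limma in the authors' deposited tables, with 266 genes (0.984%) and 2 families (0.137%) at an unadjusted p under 0.05, fewer than chance alone would give. The t values had standard deviations of 0.71 and 0.65, smaller than the standard errors imply, so these p-values may be conservative. The same standard errors enter the difference between soma and PGCs. The median log2 fold changes were -0.064 and 0.050. Erdr1 had the smallest p among genes with a positive value, at 1.58 ± 0.47, followed by Tspan1 at 2.07, Mxd4, a MYC antagonist, at 1.75, Creg1 at 1.49 and Them6 at 1.84, none of which passed in the authors' deposited table. With negative values Olfr109 stood at -2.39, Spc25, a kinetochore protein, at -1.93, Olfr705 at -2.04, Pnp2 at -1.48 and Cabp5 at -1.52, none passing in the authors' deposited table. Tet1 stood at -0.046 ± 0.47, Dazl at 0.66 ± 0.56, Ddx4 at -0.36 ± 0.49, Mael at -0.28 ± 0.51 and Stra8 at 0.98 ± 0.63 in the authors' deposited table. Sycp1 stood at -0.11 ± 0.44, Sycp3 at -0.074 ± 0.62, Pou5f1 at 0.63 ± 0.52, Gulo at 0.024 ± 0.56 and Slc23a2 at -0.27 ± 0.45 in the authors' deposited table. The 95% interval of Tet1 ran from -0.97 to 0.87. The groups are of equal size, so the sign of the PGC contrast could not be settled from the tables and is read as in soma, withdrawn minus supplied.

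With the PGC sign read as in soma, which is assumed, the retroviral classes of repeats lay above other families in PGCs and LINE-1 families below, and with the sign turned these directions, and those of the gene lists, reverse. IAP, other ERVK, ERVL, MaLR and ERV1 families had medians of 0.32, 0.31, 0.25, 0.24 and 0.35 in the authors' deposited table and lay above the other families in cameraPR (adjusted p = 0.000654, 4.3e-10, 0.00407, 0.000654 and 6.95e-09). LINE-1 families had a median of -0.17 and lay below (adjusted p = 2.62e-09). At a correlation of 0.05 the ERVL and MaLR calls ended (adjusted p = 0.0526 and 0.0628). IAPEz-int stood at 0.48 ± 0.60, MERVL-int at 0.12, GSAT_MM at 0.41 and L1Md_T at -0.023 in the authors' deposited table. The smallest p values fell to (CCTAT)n at 1.63, IAPA_MM-int at 1.40, RLTR30C_MM at 1.42, MamRep488 at 1.49 and Charlie10a at 1.36, none passing in the authors' deposited table. On the negative side UCON23 stood at -1.48, (AAGTG)n at -1.14, (AACTG)n at -0.76, tRNA-Thr-ACY_ at -1.27 and Cheshire_Mars_ at -1.30, none passing in the authors' deposited table. Among gene lists, Hox genes (median -0.40, adjusted p = 0.0372), olfactory receptor genes (median -0.25, adjusted p = 0.0203) and microRNA genes, including host transcripts (median -0.29, adjusted p = 0.0203), lay below other genes in the authors' deposited table. These 3 calls ended at a correlation of 0.05 (adjusted p = 0.496, 0.76 and 0.269). Hoxc10 and Hoxa3 stood at -0.80 and -0.62, neither passing, in the authors' deposited table.

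The last comparison tested whether the effect of withdrawal differed between soma and PGCs. The median difference, soma minus PGCs, was 1.07 over 26721 shared genes and 1.06 over 1445 shared families, with median standard errors of 0.67 and 0.64. By the Satterthwaite test 0 genes and 0 families passed (lowest adjusted p = 0.105 and 0.192), against 9209 genes and 341 families at an unadjusted p under 0.05. These unadjusted counts are more than chance alone would give, so 0 calls do not show equal effects in soma and PGCs. With each table centred on its median, 522 genes and 12 families had an unadjusted p under 0.05, fewer than chance alone would give. Lipm, a lipase, came first among genes, at 1.49 in soma and -1.23 in PGCs, and Foxq1, a forkhead factor, led the other direction, at -0.98 in soma and 1.56 in PGCs, in the authors' deposited tables. If the PGC sign is turned, an alternative chosen after the data were seen, 256 genes and 397 families differ, all higher in soma, so this result hangs on a sign that the tables do not fix.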

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

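The residual degrees of freedom, the turned PGC sign and the list test on centred t were chosen after the data were seen. No paired analysis was possible because the tables hold no values per library, and for the same reason leaving out replicates, a replicate block, limma-trend with other pseudocounts and the IgG interaction were not run. In soma 2755 genes and 658 families passed with Bonferroni, 388 genes and 130 families after centring on the median, and 9217 genes with residual degrees of freedom alone, since Bonferroni and fewer degrees of freedom raise every p. In PGCs 266 genes and 2 families had an unadjusted p under 0.05, against 0 by limma after adjustment. The difference between cell types gave 0 calls under every alternative fixed before the data were examined, and 256 genes and 397 families with the PGC sign turned. PGC gene lists gave 0 calls at a correlation of 0.05, which widens the test's error, and 1 with predicted, Rik and microRNA models left out of the background, where the microRNA list has no members left and the Hox list missed the threshold (adjusted p = 0.0545). By construction, centring reversed features below the median: in soma Dazl (-0.44), Sycp1 (-0.10), Sycp3 (-0.70), Ddx4 (-0.055), Mael (-0.13), Gulo (-0.20), Slc23a2 (-0.53), Hoxa10 (-0.23) and MERVL-int (-0.090), and above it PGC Tet1 (0.017). Soma vomeronasal receptors turned from lower to higher by ranks (adjusted p = 0.969), by fold change (adjusted p = 0.0494), without the lowest averages (adjusted p = 0.0257), against random lists (adjusted p = 0.0295) and centred (adjusted p = 0.0238). X-linked multicopy genes did so by fold change, against random lists and centred (adjusted p = 5.24e-05, 0.00832 and 0.00175), and defensins centred (adjusted p = 0.918). Predicted gene models turned likewise by fold change, without the lowest averages, against random lists and centred (adjusted p = 0.0442, 0.884, 0.0013 and 0.0393). B-type SINEs turned from higher to lower by fold change, without the lowest averages, against random lists and centred (adjusted p = 0.0429, 0.466, 0.587 and 0.000373); the cause was not tested. Of the 112 named features, 60 kept direction and side under centring, 42 kept only the direction and 10 reversed; 93 kept both with residual degrees of freedom. With the standard errors of PGC genes, which hold depth and the spread between libraries together, 0% of 2-fold and 43.5% of 4-fold changes were recovered in simulated data. Only 200 genes were changed there, so these shares do not say whether a shift of most PGC genes would be seen. For soma genes the same simulation recovered 15.5% of 2-fold changes, while 68.3% of the real soma genes passed.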

Other observations

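The tests with tRNA-derived, simple and L1Md repeats, by chromosome and by transcript class, and those of the shift's scaling and of 1 factor for all features, were chosen after the results were seen. X-linked multicopy germline genes, such as the Rhox homeobox cluster, had a soma median log2 fold change of 1.28 in the authors' deposited table, and 58 of 80 rose, also 58 adjusted over the list alone, with Rhox8 at 1.96; the list, matched by name, also takes in autosomal Slx4ip. Vomeronasal receptor genes had a median of 1.15, with 150 of 231 risen in the authors' deposited table and 149 adjusted over the list alone. Neither list passed in cameraPR (adjusted p = 0.929 and 0.984), and both lay above other genes on centred values (adjusted p = 0.00175 and 0.0238). Stromal markers had a lower median of 0.79 in the authors' deposited table (adjusted p = 0.214, and on centred values adjusted p = 0.0178). Against random lists of like average the stromal markers did not pass (adjusted p = 0.0723). Housekeeping genes had a median of 0.80, with 12 of 23 risen, oocyte genes 1.13, with 14 of 25, and zinc finger genes 1.00, with 282 of 396 risen and 2 fallen, in the authors' deposited table. Adjusted over the list alone these counts were 12, 14, 283 and 2, and none of these lists passed in cameraPR on the deposited t of all genes (adjusted p = 0.362, 0.71 and 0.984). Without the lowest averages the housekeeping list lay lower in cameraPR (adjusted p = 0.0278). Predicted gene models had a median of 1.13, with 4831 of 7158 risen and 8 fallen in the authors' deposited table, 4822 and 8 adjusted over the list alone. They did not differ in cameraPR on the deposited t (adjusted p = 0.71) and lay higher on centred values (adjusted p = 0.0393).

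Among soma repeats, tRNA-derived families had a median of 0.49 and 9 of 50 rose, and simple repeats a median of 0.69 with 141 of 282 risen and 5 fallen, in the authors' deposited table; both classes lay below other families in cameraPR (adjusted p = 3.73e-15 and 4.77e-23). The 6 L1Md families all rose, with a median of 1.38 in the authors' deposited table (adjusted p = 0.000185, and on centred values adjusted p = 0.113). B-type SINEs rose in 20 of 28 cases, with a median of 0.86 (adjusted p = 0.76), MIR families in 6 of 6, DNA transposons in 213 of 243, ancient LINEs in 11 of 11 and satellites in 7 of 7, in the authors' deposited table. The 32 ribosomal RNA genes had a median of 0.061 in soma. Autosome medians in soma ran from 0.97 on chromosome 11 to 1.09 on chromosome 17. Genes of chromosome Y over 10 kb long had 0.11 CPM per kb in supplied and 0.12 in withdrawn soma, against autosome medians of 0.508 and 1.04, and 0.231 and 0.146 in PGCs, against 0.647 and 0.635, although the libraries are labelled female; which PGC values are supplied and which withdrawn rests on the assumed sign, and copies shared with other chromosomes were not removed.

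The median soma gene stood 2.06-fold higher after withdrawal. A single factor applied to every feature alike, as the only difference between the groups, is argued against by Y-linked genes, whose median of 0.049 over 37 genes lay outside the 0.85 to 1.34 of matched random lists, and by the Hox genes, 0.80 below the median gene. These values do not test a common factor that acted beside differences between features. A different share of male cells between the groups may also lower Y-linked values, but leaves the Hox genes aside. Whether the size of the shift, 1.04, came from the scaling of the libraries, from more H3K9me2 in vitamin C withdrawn soma or from another difference between the libraries cannot be told apart, since no value in the tables is independent of the scaling.

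Features kept a similar order of log2 fold change in soma and PGCs, most clearly repeat families, with a Spearman rho of 0.642 over 1445 families and 0.194 over 26721 genes, which are not independent replicates; its sign follows the assumed sign of PGCs. Over the 722 better covered families rho was 0.844, above the bound set beforehand. Sampling noise is separate in the libraries of each cell type and would lower rho, so this value does not test what gave the order. Base composition may contribute: across simple repeats, GC share and log2 fold change had a rho of 0.231 in soma, between the bounds set beforehand, and 0.371 in PGCs, above them, and the match in sign rests on the assumed sign of PGCs, so it stays open. Neighbouring genes over 10 kb apart had a rho of 0.162 over 10307 pairs in soma, above the bound set beforehand for soma, and 0.0574 over 9675 pairs in PGCs. Regional effects within soma may give such a value, but it does not test the order shared between cell types. A shared response of both cell types to vitamin C was not tested apart from these.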
